A study of Schizosaccharomyces pombe with 6 samples.

How the data were processed

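Rad52 ChIP-on-chip was measured on 6 two-colour 44K genome tiling arrays of fission yeast (Schizosaccharomyces pombe), 3 per strain. Both strains carried cdc25-22, a temperature-sensitive mutation that holds cells before mitosis at the restrictive temperature, and 1 of them also lacked rad3, the gene of the ATR-like checkpoint kinase. Per the labels, cells were held for 4 h at 36.5 °C, released at 25 °C and given 6 mM hydroxyurea, which starves replication of nucleotides. The immunoprecipitate was in the green channel and the input in the red channel on all 6 arrays; no array had the dyes exchanged, so dye effects on single probes do not cancel within a strain. Each of the 3 slides held 1 array listed for each strain under the same replicate number. All 6 arrays were Rad52 immunoprecipitates, and none was a control immunoprecipitate. Enrichment within a strain can therefore not be told apart from unspecific enrichment.

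Agilent Feature Extraction 10.7.3.1 made the scanner files; per the file headers, slides 1 and 2 used a CGH protocol and slide 3 a ChIP protocol, with a linear dye correction and no lowess. The processed and median signals are spot intensity values per the file headers, and the processed signals were background-subtracted and dye-corrected by the authors. The deposited log ratio in each scanner file is a log10 value of red over green, that is, of input over immunoprecipitate. The deposited value table holds a linear ratio of immunoprecipitate over input with no further centring, found by comparing it with the scanner files. Of its 6 columns, 5 equal a scanner file on all 42641 probes within a tolerance of 0.001 log2, but only 1 equals the scanner file listed under the same sample.

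The ratio analysed was log2 of green over red processed signal. Control spots and outlier-flagged spots were left out, and each array was centred on its median over genomic probes. No probe had more than 1 spot. Probes were averaged in fixed 1 kb bins with at least 2 probes measured on every array, and in protein-coding genes with at least 2 probes inside. One limma 3.58.1 fit (R 4.3.3) with a mean per strain tested each strain against the array median and the rad3-deleted minus the cdc25-22 strain. Calls used a Benjamini-Hochberg threshold of 0.05, and within a strain also a mean log2 ratio of at least 0.5 in either direction for bins. Probes within 1 kb of rad3 were left out of the difference. Bin classes and 12 gene lists (202 symbols, all matched to the annotation) were tested with camera at a preset correlation of 0.01, and again with an estimated correlation. Bin labels were also rotated around each chromosome 1000 times. Rotation leaves the array values fixed, so its p concerns where a class lies and ignores the spread between arrays. Class means per array were compared with exact two-sided permutation tests, whose smallest p for 3 against 3 arrays is 0.1. All class values are relative to the mean of all bins.

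Positions were checked with Python 3.11.15 (numpy 2.4.6, pandas 2.3.3, scipy 1.17.1) by shifting probe positions along the reference ASM294v3 by up to 7 kb in 50 kb segments and taking the shift with the least spread in probe G+C share; no probe sequences were aligned. The file headers name a genome version of 2002. Array and reference positions coincided in 214 of 250 segments. On chromosome I beyond 3.75 Mb they lay 6149 to 6150 bp apart, so bins there are given in array positions and without gene names. This concerned 6063 of 42641 nuclear probes (14.2%). Those bins were left out of the class tests, so no class value covers the centromere or the right subtelomere of chromosome I. Chromosome II had 0 probes from 4500001 on, so most of its right subtelomere was not measured either. Figures were drawn with matplotlib 3.10.9. Classes were AT-rich islands (merged 500 bp windows in 50 bp steps of at least 75% A+T, outside centromeres and subtelomeres, a sequence feature shared by most fission yeast replication origins), centromeres, the outer 50 kb of chromosomes I and II, the mating-type region with 20 kb on each side, tRNA, 5S rRNA, snRNA or snoRNA genes, retrotransposon remains, intergenic regions by the direction of their neighbours, and gene interiors.

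Samples were grouped by their labels and each scanner file was placed under the sample that lists it; the tests, classes, lists and named-gene rule of this assignment were fixed before the data were examined. The second assignment, called matched here, places each scanner file under the sample whose value-table column it equals. The file listed as cdc25-22 replicate 3 equals no column and stayed where it was listed. The matched assignment was chosen after the files and their rad3 signal were seen, and every result under it is conditional on that choice. The value table itself, which needs no assignment of files, had been fixed in advance as an alternative.

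The genes named were, per comparison, the 10 with the largest and the 10 with the smallest log2 value among those past the threshold with all arrays on one side, the genes in the 5 largest runs of called bins per direction, up to 4 members of each list, and the loci rad3, rad52, cdc25, ura4, cdc22, cdc18, mik1, tlh1 and tlh2; the longest runs were added after their values were seen. Alternatives were normexp with an offset of 50 on median signals (the files hold no mean signal), loess within arrays, the value table, no centring, centring on gene interiors, arrays scaled to one MAD, quantile normalization, keeping outlier spots, leaving out dim probes, bins of 500 bp and 2 kb, single probes, removal of the A+T trend, the slide as a replicate block, both together, other thresholds, islands of at least 73% or 77% A+T, genes with 500 bp flanks, and leaving out each array in turn. A trend on A+T fitted away from islands was added after the data were seen. The fit was tested on bins simulated from the mean and spread of each bin in the matched arrays. Of 100 bins changed by 1 on the log2 scale, 76% were recovered, and of 100 changed by 0.5, 5%. Among the unchanged bins there were 2 calls. The noise was drawn independently for each bin, and far fewer bins were changed than were called in the matched arrays. The simulation therefore does not give the recovery or the false calls of that comparison. The number of arrays limits the precision. Mitochondrial probes (66 of 42707) were left out of all fits.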

Results

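Rad52, the mediator protein of homologous recombination, was mapped by chromatin immunoprecipitation in cells released from the temperature block and given hydroxyurea. These were cdc25-22 cells with rad3 (n = 3 arrays) and without it (n = 3 arrays). Values are log2 ratios of immunoprecipitate over input, relative to the median probe of each array. In the arrays listed as cdc25-22 replicates 1, 2 and 3, the median immunoprecipitate signal was 626, 676 and 670 over a background of 45, 44 and 40, and the median input signal was 846, 608 and 602 over 63, 69 and 65. In the arrays listed as rad3-deleted, the immunoprecipitate medians were 1212, 581 and 584 over 49, 43 and 38, and the input medians were 835, 562 and 798 over 72, 63 and 59. The dimmest channel was the input of the array listed as cdc25-22 replicate 2, where 84.9% of probes were well above background; in the other channels the share was 94.6% or more.

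Sequence removed by a deletion should give no DNA in either channel, so rad3 (SPBC216.05, chromosome II, 904184 to 913629, plus strand, ASM294v3) tests the labels. It carries 33 probes. In the arrays listed as cdc25-22 replicates 1 and 2, 9 and 10 of them were not well above background in both channels, and in replicate 3 none were (0). In the arrays listed as rad3-deleted the numbers were 0, 0 and 9. Of the 10 dim probes in the file listed as cdc25-22 replicate 2, the array with the dimmest input, 3 lay outside the lost stretch described next. A block of 7 probes from 909475 to 911114 had lost its input DNA on the same 3 arrays, with log2 input relative to the array median of -5.81 and -3.34 (listed as cdc25-22 replicates 1 and 2) and -6.07 (listed as rad3-deleted replicate 3), against -0.49, -0.47 and -0.38 on the other arrays. The lost stretch was not the same on all 3. The files listed as cdc25-22 replicate 1 and rad3-deleted replicate 3 lacked 9 adjoining probes, centred at 909041 to 911085, while the file listed as cdc25-22 replicate 2 kept input signal at the first 2 of them (-0.49 and -1.14). Most of rad3 still gave DNA: over the 24 rad3 probes outside this stretch the mean input was -0.22, -0.42 and -0.33 on these 3 arrays, against -0.22, -0.11 and -0.26 on the others. The missing block thus went against the labels of 4 of 6 arrays. The value table paired the same 4 files with the opposite strain: its columns for replicates 1 and 2 of each strain equal the files listed for the other strain. With the files matched to the columns, the number of dim rad3 probes was 0.0 ± 0.0 (SD, n = 3) in cdc25-22 and 9.33 ± 0.58 (SD, n = 3) in rad3-deleted arrays (exact two-sided permutation p = 0.1). With the files as listed it was 6.33 ± 5.51 and 3.0 ± 5.2 (SD, n = 3 each, exact permutation p = 0.7). The column for cdc25-22 replicate 3 equals no scanner file, and the file listed there, which has rad3 signal, equals no column.

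**Figure D1:**
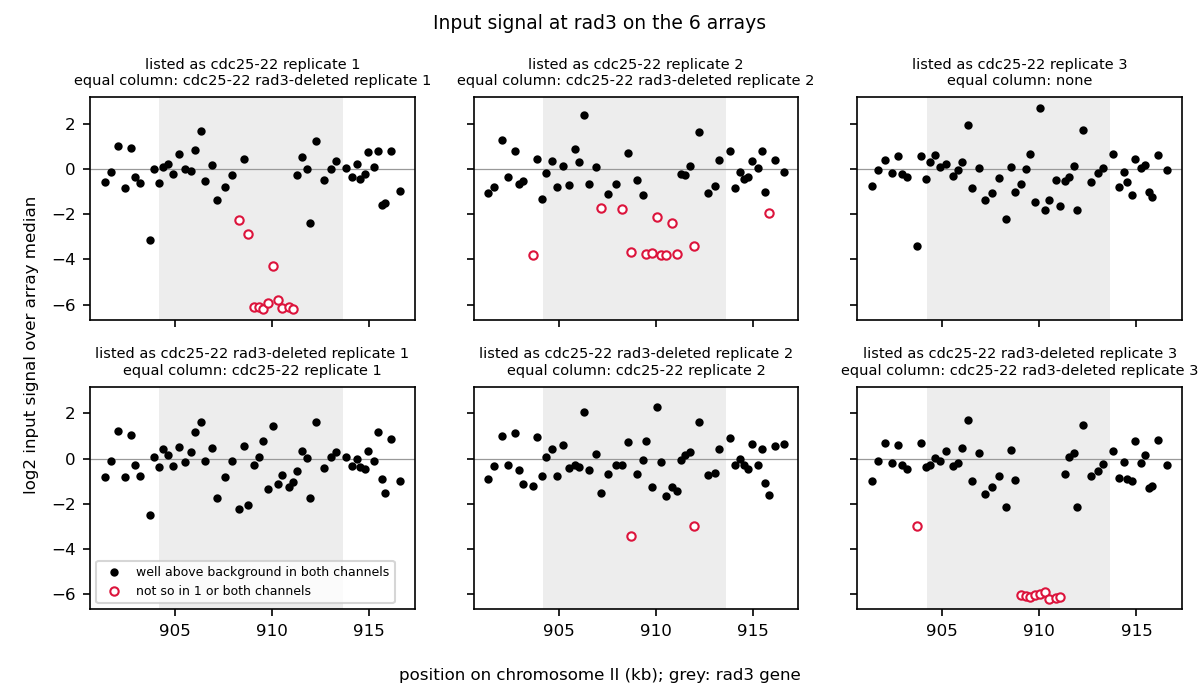
Log2 input signal of each probe at rad3 and its flanks against position on chromosome II, relative to the array median. Each of the 6 arrays is shown under its listed name. The 7-probe block from 909475 to 911114 lacks input in the arrays listed as cdc25-22 replicates 1 and 2 and rad3-deleted replicate 3.

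Under the listed names, almost no single locus could be called in either strain. The classes above the genome mean were nearly the same for both sets of arrays: AT-rich islands, centromeres, subtelomeres, the mating-type region, convergent and tandem intergenic regions, and the genes of tRNA, 5S rRNA and small nuclear or nucleolar RNA. Islands were defined by sequence and not by mapped replication origins. Since the listed names go against the rad3 signal, these sets each mix arrays with and without the rad3 block. In the arrays listed as cdc25-22, limma called 0 of 11917 bins enriched and 0 depleted (2125 bins at an unadjusted p under 0.05) and 0 of 4127 genes (728 unadjusted). In those listed as rad3-deleted it called 1 bin enriched and 0 depleted (1377 unadjusted), on chromosome I from 4002001 to 4003000 in array positions, at 1.36 ± 0.04 (SD, n = 3). The 3 genes called there were psu1 (SPAC1002.13C, I, 1821401 to 1823430), a cell wall protein gene, at 0.87 ± 0.10 (adjusted p = 0.0418), ecm33 (SPAC1705.03C, I, 1569613 to 1571589), another cell wall gene, at 0.78 ± 0.08 (adjusted p = 0.0418), and rec15 (SPBC1711.14, II, 2161487 to 2162200), a meiotic recombination gene, at 0.69 ± 0.07 (SD, n = 3, adjusted p = 0.0461). In the arrays listed as cdc25-22 the same genes stood at 0.63 ± 0.20, 0.63 ± 0.07 and 0.65 ± 0.08 with adjusted p of 0.0715, 0.067 and 0.067. None of the 3 passed on leaving out any 1 array; without the array listed as rad3-deleted replicate 2 the adjusted p of each was 0.246. With the slide as a replicate block it was 0.686, and without dim probes psu1 and ecm33 were at 0.0627 and 0.226. Islands were at 0.22 (adjusted p = 8.41e-06) and 0.16 (adjusted p = 0.00016), centromeres at 0.74 and 0.65, subtelomeres at 0.51 and 0.31, convergent regions at 0.26 and 0.20, tandem regions at 0.16 and 0.11, and 5S rRNA genes at 0.43 and 0.40 in the listed cdc25-22 and rad3-deleted arrays. The mating-type region was at 0.21 and 0.14, with an adjusted p of 0.0643 and 0.0639 by rotating bin labels. None of these class calls held with an estimated correlation (lowest adjusted p = 0.0926 and 0.101), and islands in the listed rad3-deleted arrays were at 0.08 (adjusted p = 0.0718) with the A+T trend removed. Of the gene lists, nutrient transporters were higher in both (0.28 and 0.16, adjusted p = 0.000159 and 0.0146, and 0.58 and 0.564 with an estimated correlation), as were glycolysis genes (0.23 and 0.18, adjusted p = 0.00204 and 0.04, and 0.616 and 0.564 with an estimated correlation). Ribosomal protein genes were higher in the listed cdc25-22 arrays (0.09, adjusted p = 0.00296, 0.616 with an estimated correlation, 0.144 without listed replicate 3, 0.0541 without dim probes) and MBF targets, the S phase genes, in the listed rad3-deleted arrays (0.10, adjusted p = 0.0465, 0.564 with an estimated correlation). Of these lists 0 members were called over all genes; adjusted over the list alone, 7 and 5 transporters and 5 ribosomal protein genes were higher. The rad3-deleted list calls were lost without its listed replicate 2 (adjusted p = 0.173 each), and those of glycolysis and MBF targets also without replicate 1 (0.266 each). Without the array listed as rad3-deleted replicate 3, islands and subtelomeres in that strain went to -0.07 and -0.11, and 298 bins were called enriched and 116 depleted in the arrays listed as cdc25-22.

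The main comparison asks where Rad52 sits differently when the checkpoint kinase is missing. As listed, no bin and no gene differed. limma called 0 of 11905 bins (128 at an unadjusted p under 0.05, 1.1%) and 0 of 4127 genes (59 unadjusted), and the smallest adjusted p of a bin was 1. Subtelomeres were lower by camera in the arrays listed as rad3-deleted, at -0.20 (adjusted p = 0.025), but the 3 slides gave -0.84, -1.07 and 1.30, so only 2 of 3 showed the direction. The exact permutation p was 1 (n = 3 each), the adjusted p was 0.0633 with the slide as a replicate block, and 0.759 with an estimated correlation. The camera call was lost without listed cdc25-22 replicate 1 (-0.09, adjusted p = 0.313) or 2 (0.02, 0.874). It was also lost without listed rad3-deleted replicate 1 (0.01, 0.945) or 2 (0.01, 0.909). Without replicate 3 of cdc25-22 or of rad3-deleted it held (-0.53 and -0.63). Nutrient transporters were lower as a list, at -0.11 (adjusted p = 0.0151, 0.862 with an estimated correlation, and 0.153, 0.0732, 0.0726 and 0.328 without the arrays listed as cdc25-22 replicates 1 and 2 and rad3-deleted replicates 1 and 3), with 0 of 15 members called over all genes and 0 adjusted over the list alone; one MAD and quantile normalization ended the call. Islands were at -0.06 (adjusted p = 0.167). Camera called them lower without the array listed as rad3-deleted replicate 3 (-0.28, adjusted p = 5.76e-13) or cdc25-22 replicate 3 (-0.15, adjusted p = 0.00898). It called them higher without the array listed as rad3-deleted replicate 2 (0.07, adjusted p = 0.0335). On the 3 slides islands were at -0.26, -0.49 and 0.58. The same slide pattern, with the third slide opposite to the others, held for the mating-type region (-0.25, -0.23 and 0.29) and for gene interiors (0.07, 0.15 and -0.16). On slides 1 and 2 the listed names go against the rad3 signal. With those files matched, the signs there turn by construction, and islands were at 0.26, 0.49 and 0.58. Since each listed set mixes arrays with and without the rad3 block, the lack of calls does not answer the question asked.

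What follows uses the arrays matched to the value table, an assignment chosen after the files and the rad3 signal were seen; the directions hold only if it is right. In arrays matched to cdc25-22, Rad52 ChIP signal was, of the bin classes, highest at centromeres and at genes of small untranslated RNAs, and AT-rich islands showed no gain except in the value table. Without a control immunoprecipitate, whether the signal at the classes, genes and lists of a strain is specific to Rad52 was not tested. limma called 257 of 11917 bins enriched and 19 depleted (2204 unadjusted), and 84 genes higher and 9 lower. Over the alternatives with all arrays, other thresholds and bin sizes included, enriched bins numbered 19 to 576 and depleted bins 0 to 95. Leaving out cdc25-22 replicate 1, 2 or 3 gave 107, 117 or 139 enriched and 11, 6 or 2 depleted bins. Centromeres stood at 0.54 ± 0.12 (SD, n = 3, adjusted p = 4.12e-16), with 9 of 21 bins enriched. The 5S rRNA genes stood at 0.40 ± 0.11 (adjusted p = 9.74e-17, 14 of 35 bins), tRNA genes at 0.29 ± 0.12 (adjusted p = 6.22e-24, 21 of 120 bins) and small nuclear or nucleolar RNA genes at 0.25 ± 0.09 (adjusted p = 3.82e-11, 10 of 62 bins). Each was above the genome mean on 3 of 3 arrays, and each had an adjusted p of 0.0832 with an estimated correlation. Islands were at -0.03 ± 0.07 (SD, n = 3, adjusted p = 0.157), with -0.03, -0.10 and 0.04 on the arrays. Islands were called lower by rotation (0.00267), which ignores that spread, and were at -0.07 with 0.0086 without cdc25-22 replicate 3. In the value table they were at 0.08, a called gain (adjusted p = 0.00386) that came from the column for replicate 3, which equals no scanner file (0.37, against -0.03 and -0.10 in the columns for replicates 1 and 2). Subtelomeres were at -0.13 ± 0.02 and retrotransposon remains at -0.11 ± 0.09.

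Among runs of called bins in named parts, the highest mean of these arrays lay over snoU14, a small nucleolar RNA gene, on chromosome II from 1308001 to 1309000 at 1.35 ± 0.26 (SD, n = 3). Next among these runs came a 5S rRNA gene (SPRRNA.06) on chromosome III from 1702001 to 1703000 at 1.20 ± 0.35, a cluster of snoRNA genes (snoZ7 to snoZ3) beside psf3 on chromosome I from 527001 to 528000 at 1.05 ± 0.34, and htb1 with sec5 on chromosome III from 1413001 to 1414000 at 1.05 ± 0.19. The widest run covered 7 kb of the chromosome II centromere, from 1621001 to 1628000, at 1.01 ± 0.15. Among protein-coding genes the top values were rps3 (SPBC16G5.14C, II, 4238212 to 4239339), a ribosomal protein gene, at 0.86 ± 0.42 (adjusted p = 0.00803), ole1 (SPCC1281.06C, III, 1392544 to 1394876), the fatty acid desaturase gene, at 0.81 ± 0.14 (adjusted p = 0.00325), and psu1 at 0.80 ± 0.15 (adjusted p = 0.00405). The histone H2B gene htb1 (SPCC622.09, III, 1412359 to 1413677) was at 0.80 ± 0.25 (adjusted p = 0.00929) and the actin gene act1 (SPBC32H8.12C, II, 1475485 to 1477333) at 0.78 ± 0.10 (SD, n = 3, adjusted p = 0.00772). Of these, ole1 and psu1 kept the call without any 1 array; rps3 lost it without cdc25-22 replicate 1 (adjusted p = 0.0633), htb1 without replicate 1 or 2 (adjusted p = 0.0636 or 0.0894), and act1 without replicate 2 (adjusted p = 0.0713). The lowest genes were SPAC22H10.06C at -0.66 ± 0.38, wdr83 (SPBC713.05) at -0.62 ± 0.30 and SPAC1002.20 at -0.58 ± 0.28, and none of the 3 kept the call without cdc25-22 replicate 3 (adjusted p = 0.0969, 0.153 and 0.11).

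In arrays matched to cdc25-22, 6 gene lists stood above all genes, and none of these calls held with an estimated correlation. Of 77 measured cytosolic ribosomal protein genes, 7 were higher and 0 lower over all genes, and 22 and 0 adjusted over the list alone (list mean 0.15 above all genes, adjusted p = 1.09e-06, 0.293 with an estimated correlation). Of 14 glycolysis genes, 5 were higher and 0 lower over all genes, and 8 and 0 adjusted over the list alone (0.29, adjusted p = 7.92e-05, 0.293 with an estimated correlation). They were led by pdc101 (0.73 ± 0.17) and eno101 (0.63 ± 0.21), genes of ethanol formation and glycolysis that lost the call without cdc25-22 replicate 1 (adjusted p = 0.141 and 0.23). Of 6 histone genes, 1 was higher and 0 lower over all genes, and 4 and 1 adjusted over the list alone (0.37, adjusted p = 0.00475, 0.293 with an estimated correlation, 0.0925 without dim probes). Of 17 targets of MBF, the transcription factor of the S phase genes, 2 were higher and 0 lower over all genes, and 3 and 0 adjusted over the list alone (0.13, adjusted p = 0.00475, 0.293 with an estimated correlation, 0.0666 in the value table). The 2 were the replication licensing gene cdc18 (SPBC14C8.07C, II, 2215955 to 2217984) at 0.59 ± 0.02 and tos4 (SPAP14E8.02, I, 1922543 to 1924915) at 0.57 ± 0.11 (adjusted p = 0.0636 without cdc25-22 replicate 1). Of 15 nutrient transporters, 5 were higher and 0 lower over all genes, and 5 and 0 adjusted over the list alone (0.18, adjusted p = 0.00475, 0.293 with an estimated correlation). Of 12 cell wall and septum genes, 2 were higher and 0 lower over all genes, and 3 and 1 adjusted over the list alone (0.20, adjusted p = 0.00701, 0.293 with an estimated correlation and 0.0517 without cdc25-22 replicate 2). The replication machinery (29 genes, -0.02, adjusted p = 0.618) and the recombination and checkpoint genes (20 genes, 0.02, adjusted p = 0.66) did not stand out, with psf3 the 1 gene called among them over all genes and adjusted over the list alone (0.48 ± 0.19, adjusted p = 0.252 without cdc25-22 replicate 1). Ribosomal, histone and hexose transporter paralogs share sequence that probes can bind.

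In arrays matched to rad3-deleted, Rad52 signal lay over AT-rich islands and subtelomeres as well as centromeres and small RNA genes, while gene interiors lay below the mean of all bins. limma called 1530 of 11917 bins enriched and 554 depleted (5741 unadjusted), and 817 genes higher and 883 lower. The depleted bins numbered 910 without rad3-deleted replicate 1 and 382 without replicate 3. Over the alternatives with all arrays, other thresholds and bin sizes included, they numbered 1 to 2675. With an estimated correlation no class passed (lowest adjusted p = 0.063). Subtelomeres stood at 0.95 ± 0.21 (SD, n = 3, adjusted p = 3.49e-20), with 30 of 38 bins enriched. Centromeres stood at 0.85 ± 0.12 (adjusted p = 2.51e-06, 10 of 21 bins), 5S rRNA genes at 0.43 ± 0.14 (adjusted p = 3.22e-06), islands at 0.41 ± 0.20 (adjusted p = 2.68e-14, 202 of 487 bins) and the mating-type region at 0.30 ± 0.02 (adjusted p = 7.1e-05, 0.0643 by rotation). The median centromere bin was at 0.34 over the array median, and 7 of the 21 bins lie in the chromosome II run given below. Gene interiors were at -0.11 ± 0.06 (adjusted p = 2.61e-05), a call lost with the A+T trend removed (-0.05). The strongest run was the chromosome II centromere from 1621001 to 1628000 at 2.03 ± 0.24, followed by 2 kb of the chromosome III centromere from 1097001 to 1099000 at 1.98 ± 0.04 and by 9 kb on chromosome I from 1950001 to 1959000, with pcs2 and hsr1, at 1.80 ± 0.34 (SD, n = 3). The highest genes were mug147 (SPBC56F2.06) at 1.79 ± 0.18, wwm3 (SPBC660.05, II, 202281 to 203623) at 1.71 ± 0.46 and SPAC17A2.10C at 1.61 ± 0.51. The lowest were smb1 (SPAC26A3.08, I, 3347004 to 3348195), a spliceosomal protein gene, at -0.95 ± 0.45, wdr83 at -0.79 ± 0.29 and sap10 (SPBC211.05) at -0.78 ± 0.15, and the B-type cyclin gene cig1 (SPCC4E9.02, III, 1227226 to 1229303) was at -0.73 ± 0.04. Nutrient transporters were the 1 list called (0.26, adjusted p = 0.0269), with 9 higher and 2 lower of 15 over all genes, and 9 and 2 adjusted over the list alone; the adjusted p was 0.0728 without rad3-deleted replicate 1, 0.104 without replicate 2, 0.054 under normexp and 0.915 with an estimated correlation.

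Between the strains, the matched rad3-deleted arrays had more Rad52 signal, relative to all bins, at AT-rich islands, at subtelomeres and in the regions between genes. limma called 1453 of 11905 bins higher and 455 lower in rad3-deleted arrays (3783 unadjusted, 31.7%); in the value table the counts were 934 and 83 of 12038. Of the bins in both, 907 were called higher and 67 lower by both. The lower calls depended on single arrays: 113, 187 or 294 without cdc25-22 replicate 1, 2 or 3, and 911, 125 or 182 without rad3-deleted replicate 1, 2 or 3. They numbered 852 with the slide as a replicate block. Centring moved the balance, from 63.8% of calls higher with no centring to 85.6% with centring on gene interiors, against 76.2%. Islands rose by 0.44 over the genome mean, from -0.03 ± 0.07 to 0.41 ± 0.20 (SD, n = 3 each, adjusted p = 4.14e-17), with 0.26, 0.49 and 0.58 on the 3 slides. The exact permutation p was 0.1, and the adjusted p was 0.241 with an estimated correlation and 0.002 by rotating bin labels. The unadjusted rotation p of 0.001 was the smallest that 1000 rotations can give, and it ignores the spread between arrays. The value table gave 0.34. Subtelomeres rose by 1.07, a 2.1-fold change, from -0.13 ± 0.02 to 0.95 ± 0.21 (adjusted p = 6.95e-26, 0.113 with an estimated correlation), with 0.84, 1.07 and 1.30 on the slides, and 31 of 38 bins higher and 0 lower. Of these bins, 18 form a single run on chromosome II from 30001 to 48000. Adjoining bins are not independent, and the class covers few chromosome ends.

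**Figure D2:**
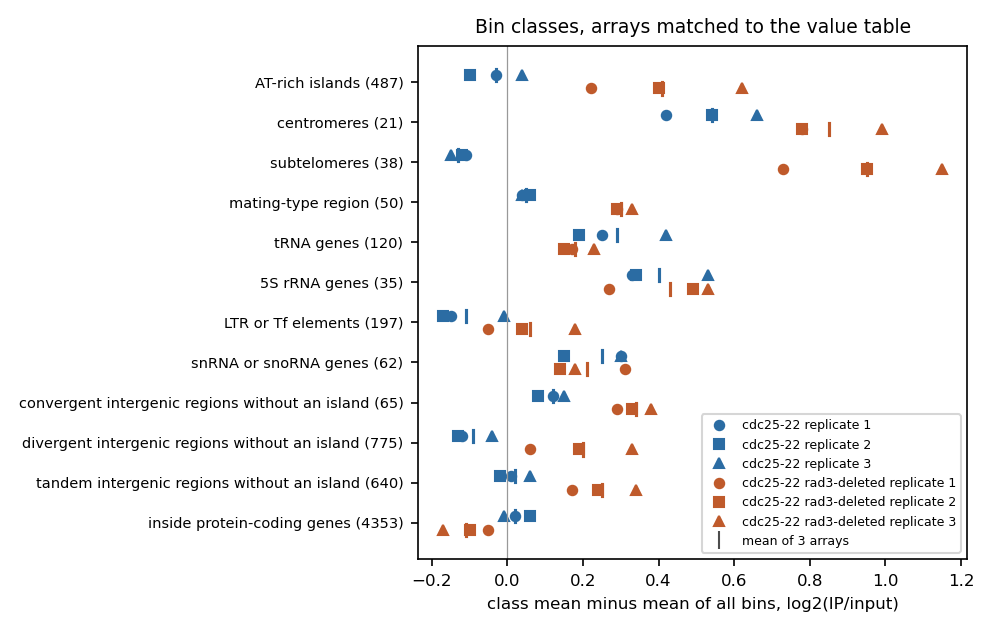
Mean log2 ratio of immunoprecipitate over input per array (points) for each bin class relative to all bins, with arrays grouped by the matched assignment. Islands lie between 0.22 and 0.62 and subtelomeres between 0.73 and 1.15 in the rad3-deleted arrays, against at most 0.04 and -0.11 in cdc25-22.

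Of 314 islands with a tested bin, 149 (47.5%) held a bin that was higher in the matched rad3-deleted arrays and 3 a lower one. Bins within 3 kb of an island centre made up 44% of the 1215 higher bins in named parts, and 17.1% of the 10207 tested. The difference fell off with distance, from 0.49 within 1 kb to 0.30, 0.20 and 0.11 in the next 3 kb and to -0.07 at 20 to 40 kb. In the cdc25-22 arrays the profile was flat (-0.03 ± 0.05 within 1 kb). None of the class calls that follow passed with an estimated correlation (lowest adjusted p = 0.113). Intergenic regions without an island rose as well: divergent ones by 0.29 (adjusted p = 1.53e-11, 213 of 775 bins), tandem ones by 0.23 (adjusted p = 1.58e-07, 162 of 640) and convergent ones by 0.22 (adjusted p = 0.00915, 17 of 65). Gene interiors stood 0.13 lower relative to all bins (adjusted p = 1.58e-07), on 3 of 3 slides. Values relative to all bins balance, so a gain elsewhere lowers this one, and a loss inside genes was not shown. Retrotransposon remains rose by 0.17 (adjusted p = 0.000983), and were at 0.09 with the A+T trend removed (adjusted p = 0.0583). The mating-type region was 0.26 higher (adjusted p = 0.000637), but with an adjusted p of 0.115 by rotation. Centromeres were 0.31 higher (adjusted p = 0.0124), but -0.01 under quantile normalization and 0.09 with one MAD (adjusted p = 0.448). The median centromere bin differed by 0.18. The call was also lost by rotation (0.124), with the A+T trend removed (0.13, 0.251), in 2 kb bins (0.164) and without dim probes (0.0799). The genes of 5S rRNA (0.03, adjusted p = 0.841), tRNA (-0.11, adjusted p = 0.0631) and small nuclear or nucleolar RNA (-0.04, adjusted p = 0.841) were enriched in both strains, except that tRNA genes in rad3-deleted arrays lost the call with the A+T trend removed (0.08, adjusted p = 0.101). For tRNA genes the difference depended on the setting. They were called lower in rad3-deleted arrays by rotation (adjusted p = 0.015), in the value table (-0.10, adjusted p = 0.0468), with one MAD (-0.20, adjusted p = 0.000145), quantile normalization (-0.23, adjusted p = 1.48e-05) or the A+T trend removed (-0.22, adjusted p = 4.29e-05), and without cdc25-22 replicate 1 or 2 or rad3-deleted replicate 3 (adjusted p = 0.0295, 0.00655 and 0.0105). Loess, kept outlier spots, 500 bp bins and single probes called them lower as well. Quantile normalization also called 5S rRNA genes lower (-0.17, adjusted p = 0.0226). The convergent call was lost with one MAD, quantile normalization, 2 kb bins or the A+T trend removed.

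**Figure D3:**
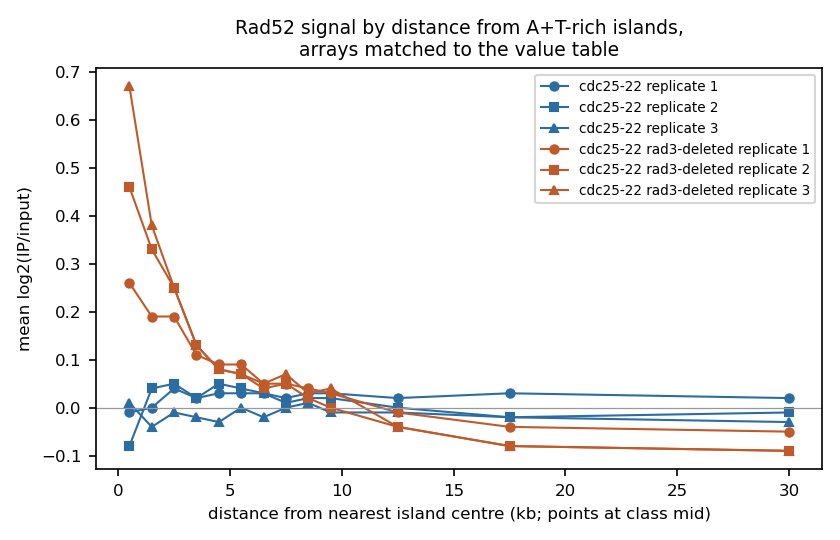
Mean log2 ratio of immunoprecipitate over input per array against distance from the nearest AT-rich island centre in kb, arrays grouped by the matched assignment. The rad3-deleted arrays average 0.46 within 1 kb and 0.23 at 2 to 3 kb, and the cdc25-22 arrays -0.03 and 0.03.

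The bins higher in the matched rad3-deleted arrays formed 543 runs with a median of 2 kb, and the lower bins 334 runs with a median of 1 kb. The strongest run in a named part covered 7 kb of chromosome II from 4105001 to 4112000, at mug147, a tRNA gene for glutamate and SPBC56F2.05C, with 0.08 ± 0.15 in cdc25-22 and 1.99 ± 0.23 in rad3-deleted arrays (SD, n = 3 each, 3.76-fold). On chromosome I, rds1 with SPAC343.21 and SPAC343.20 (1664001 to 1668000) rose by 1.75, and the iron regulator gene fep1 (440001 to 445000) by 1.73. Further runs lay on chromosome I at 5551001 to 5553000 (1.86) and 5260001 to 5270000 (1.83) in array positions. The longest run took 24 kb of the left end of chromosome I, from 68001 to 92000, at -0.10 ± 0.04 and 1.27 ± 0.32. It holds SPAC977.17, SPAPJ695.02, SPAPJ695.01C, the hexose transporter gene ght3 and the heme uptake genes shu1 and str3. At the left end of chromosome II, 18 kb from 30001 to 48000 with ght7, grt1 and fah1 rose by 1.46. The lower runs were short: SPBTRNALEU.09 with mis20 (II, 3209001 to 3210000) at -0.91, gly1 (I, 2508001 to 2509000) at -0.86, and rga2 with cnt6 (I, 3352001 to 3353000) at -0.85, with the longest over cnt6, the exoribonuclease gene dhp1 and SPAC26A3.11 (I, 3355001 to 3361000) at -0.70.

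**Figure D4:**
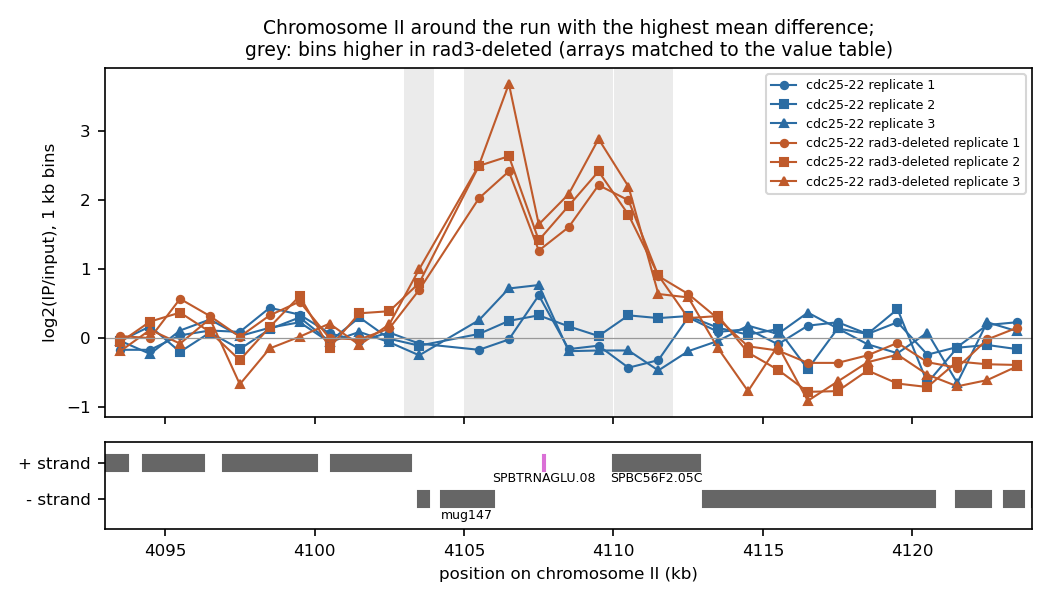
Log2 ratio of immunoprecipitate over input in 1 kb bins per array around the strongest run, on chromosome II, with annotated genes. Arrays are grouped by the matched assignment. The 7 kb run from 4105001 to 4112000 averages 1.99 in rad3-deleted and 0.08 in cdc25-22 arrays.

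By gene, 437 were higher and 227 lower in the matched rad3-deleted arrays. The higher genes numbered 230 without cdc25-22 replicate 1 and 219 without rad3-deleted replicate 2. The lower ones numbered 29, 70 or 149 without cdc25-22 replicate 1, 2 or 3, and 431, 28 or 73 without rad3-deleted replicate 1, 2 or 3. The largest rise was in mug147 (II, 4104214 to 4105988), from 0.01 ± 0.19 to 1.79 ± 0.18 (3.43-fold, SE 0.13, adjusted p = 0.000232). SPAPJ695.01C and SPAPJ695.02, in the 24 kb run at the left end of chromosome I, rose by 1.77 (SE 0.17) and 1.70 (SE 0.15), wwm3 by 1.62, stg1 (SPAC4F8.10C) by 1.62, arv1 (SPAPB1A10.15) by 1.59 and ddr48 (SPAC23H3.15C) by 1.56. The phosphatidylinositol synthase gene pis1 (SPAC1D4.08, I, 650473 to 652224) rose by 1.49, the RNA polymerase I subunit gene rpa12 (SPCC1259.03) by 1.48 and are1 (SPAC13G7.05) by 1.44. These 10 kept the call without any 1 array. Among the lower genes, htb1 fell by 0.78 (SE 0.17, adjusted p = 0.014), from 0.80 ± 0.25 to 0.02 ± 0.32, and act1 by 0.74 (SE 0.16, adjusted p = 0.0123), from 0.78 ± 0.10 to 0.03 ± 0.34. The gene lsm3 (SPBC9B6.05C) fell by 0.75, dhp1 (SPAC26A3.12C) by 0.69, the copper transporter gene ctr4 (SPCC1393.10) by 0.69 and cnt6 (SPAC26A3.10) by 0.68. SPAC26A3.11 (-0.79), ina17 (-0.69), guk1 (-0.67) and isa1 (-0.67) lost the call without cdc25-22 replicate 1 (adjusted p = 0.0645, 0.0772, 0.134 and 0.0702).

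No gene list differed as a whole between the matched strains; the lowest adjusted p was 0.0832, for ribosomal protein genes (-0.16, 1 higher and 4 lower over all genes, 1 and 1 adjusted over the list alone), and 0.968 for every list with an estimated correlation. Single members went both ways. In the replication machinery (2 higher, 3 lower over all genes, 3 and 4 adjusted over the list alone), the helicase subunit gene mcm7 (SPBC25D12.03C, II, 3717577 to 3720039) rose by 0.83 (SE 0.15, adjusted p = 0.00465). The polymerase delta subunit gene cdc27 rose by 0.52, while mcm6 fell by 0.50 and rad4 by 0.46. Of these 4, mcm7 kept the call without any 1 array, and without cdc25-22 replicate 1 the adjusted p was 0.066 for cdc27, 0.0996 for mcm6 and 0.0576 for rad4. Of the recombination and checkpoint genes (1 and 1 over all genes, 1 and 0 adjusted over the list alone), mre11 (SPAC13C5.07, I, 436179 to 439980), of the break repair complex, rose by 0.79 (SE 0.13, adjusted p = 0.00329), and exo1 (-0.36) lost its call without cdc25-22 replicate 1 (adjusted p = 0.122). Of the MBF targets (1 and 2 over all genes, 2 and 3 adjusted over the list alone), tos4 fell by 0.57 (SE 0.11, adjusted p = 0.00528), and suc22 (0.44) and ams2 (-0.41) lost the call without cdc25-22 replicate 1 (adjusted p = 0.115 and 0.189). Glycolysis (2 and 2 over all genes, 3 and 3 adjusted over the list alone) held eno102 (0.53), pdc201 (0.49), pfk1 (-0.63) and fba1 (-0.65), and without cdc25-22 replicate 1 their adjusted p were 0.0628, 0.0645, 0.0996 and 0.134. The transporters (2 and 0 over all genes, 2 and 0 adjusted over the list alone) were ght3 (0.88, SE 0.15, adjusted p = 0.00391) and amt1 (0.61, SE 0.12, adjusted p = 0.00719). Of 6 histone genes htb1 was the 1 called lower (0 and 1 over all genes, 1 and 3 adjusted over the list alone, list -0.35, adjusted p = 0.479). The cell wall list (1 and 2 over all genes, 1 and 2 adjusted over the list alone) was at -0.11 (adjusted p = 0.479). Of the loci fixed in advance, rad52 (0.03, adjusted p = 0.901), cdc25 (-0.10, adjusted p = 0.588), ura4 (-0.11, adjusted p = 0.518), cdc18 (-0.30, adjusted p = 0.0644), mik1 (0.35, adjusted p = 0.0559) and the subtelomeric helicase gene tlh1 (0.35, adjusted p = 0.0623) were not called different; cdc22 and tlh2 were not measured.

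The spread of the log2 ratio over bins, which sets how far all values can move, was 0.262 ± 0.0467 in arrays matched to cdc25-22 and 0.470 ± 0.0998 in those matched to rad3-deleted (SD, n = 3 each, exact permutation p = 0.1). As listed it was 0.375 ± 0.0865 and 0.357 ± 0.192 (exact permutation p = 0.9). Across bins, which are not independent replicates, arrays correlated with r of 0.30 to 0.54 within matched cdc25-22, 0.74 to 0.83 within matched rad3-deleted, and 0 to 0.30 between the strains.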

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

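Of the tests in this part, the 2 on base composition were chosen before their results were seen, and those on the island flanks, the range of the arrays, the input at islands, the extra DNA, the exchanged files and the splits of the arrays only afterwards. The strain names below are those of the matched assignment unless an array is called listed.

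The first pattern is the rad3 signal, missing over part of the gene, which went against the listed names. The files listed as cdc25-22 replicates 1 and 2 each had at least 9 of 33 rad3 probes that were not well above background, and those listed as rad3-deleted replicates 1 and 2 had 0, so a single wrong name does not account for it: the exchange has a partner in each group. The value table pairs these 4 files with the strain their rad3 signal fits, which was known when the test was made. A candidate explanation is therefore that the files of replicates 1 and 2 were exchanged between the strains on deposit. The columns of these 4 samples each equal, on all probes, a file whose rad3 signal fits the strain. This argues against an exchange of cells or arrays that the value table would have carried along. How the files came to be listed so stays open, and no biological explanation was tested. The 6 arrays make 10 splits, too few for a share under 0.05. As listed, 0 bins differed by limma (128 at an unadjusted p under 0.05), so that all 10 splits gave as many was fixed and tests nothing; the highest other split gave 1908. That was the split into matched groups, with 1908 bins and 664 genes, where 1 of 10 splits gave as many in each case and the highest other gave 0.

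The second pattern is the difference between the strains at AT-rich islands, 0.44 on the log2 scale and with a test of the difference past its threshold (adjusted p = 4.14e-17; 0.241 with an estimated correlation). With each array's A+T trend, fitted away from islands, removed it was 0.29 (SD over slides 0.0919). It was still called (adjusted p = 4.95e-08, within 1.13e-20 to 0.241 over the alternatives) but not above the bound of 0.2 by more than its spread. With the trend fitted on islands as well, the correction fixed in advance, it was 0.26 (adjusted p = 4.93e-07). Islands and base composition thus cannot be told apart at the islands themselves. In the flanks at 2 to 3 kb, whose A+T share is 0.1 points from that at 20 to 40 kb, the excess was 0.27 (SD 0.0493), which argues against base composition there. With all arrays scaled to one MAD, which evens out their range, the difference was 0.38 (SD 0.0805). Given array spreads of 0.262 in cdc25-22 and 0.470 in rad3-deleted, such scaling could hardly bring it to 0.2. It therefore cannot decide on a wider range of the rad3-deleted arrays. The input at islands was 0.08 higher, not lower, which argues against a loss of input DNA. Open are the strain difference itself, a wider range of the rad3-deleted arrays, and base composition at island centres. Which of them acts was not tested. For the strain difference, a hypothesis is that forks stalled near origins by hydroxyurea may gather more Rad52 without Rad3. The hypothesis would need arrays of both strains without hydroxyurea, which the series lacks.

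The third pattern lies at the subtelomeres, where the strains differed by 1.07 in immunoprecipitate over input, and where the input channel, in the report only the denominator of the ratios and a measure of rad3, was higher when taken alone by 0.53 in the rad3-deleted arrays (0.55, 0.48 and 0.55 on the 3 slides; exact permutation p = 0.1; camera p = 3.77e-45, and 7.76e-05 with an estimated correlation). No single bin of the input differed by limma (0 of 11905; 289 at an unadjusted p under 0.05). With the A+T trend of the input removed, the value was 0.51 (SD 0.0302), which argues against base composition. A candidate explanation is extra DNA where Rad52 signal rose, and it predicts that the input rises with the ratio at islands too: over 487 island bins, which are not independent, Spearman's rho was 0.49 (Pearson's r 0.56; rotation p = 0.001, the smallest that 1000 rotations can give), and within slides 0.36, 0.15 and 0.29. Between the ratio of one slide and the input of another, which share no channel, it was 0.33 to 0.51. Over all 10195 bins in named parts rho was 0.19, under the bound of 0.2 set for islands, so the relation was not shown for the genome at large. At centromeres, where the ratio was 0.31 higher, a call that several alternatives ended, the input differed by 0 (0.02, -0.03 and 0 on the slides), so extra DNA was not seen there. A difference in cell cycle position or in DNA recovery between the strains was not tested and stays open.

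A further signal was found in the value-table column for cdc25-22 replicate 3, which equals no scanner file. Its islands stood at 0.37, against -0.03 and -0.10 in the other 2 cdc25-22 columns and 0.23, 0.40 and 0.62 in the rad3-deleted columns, while its subtelomeres were at -0.03. Its origin was not tested.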

How the results depend on the processing

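Chosen after the data were seen were the matched assignment, with every alternative under it, and the A+T trend fitted away from islands; the other alternatives had been fixed in advance. A value whose sign changed while neither value passed the threshold is counted as unchanged. Causes of the changes were not tested unless stated.

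The counts of bins and genes called different between the strains changed most with the assignment of the files. The value table differs from the listed files in the assignment, in cdc25-22 replicate 3, whose column equals no scanner file, and in keeping outlier spots. From the listed files to the value table, enriched and depleted bins went to 119 and 3 in cdc25-22 and 1529 and 562 in rad3-deleted, bins higher and lower between the strains to 934 and 83, and genes to 285 and 41; subtelomeres (-0.08) and divergent regions (-0.05) in cdc25-22 and retrotransposon remains in rad3-deleted (0.06) changed sign. So did the differences at islands (0.34), centromeres (0.25), subtelomeres (1.02), the mating-type region (0.25), retrotransposon remains (0.14), convergent (0.19), divergent (0.24) and tandem (0.20) regions, gene interiors (-0.11) and the transporter list (0.12). With the files matched, the counts were 257, 19, 1530, 554, 1453, 455, 437 and 227 in the same order. Reversed with the matched files were islands (-0.03), subtelomeres (-0.13), divergent regions (-0.09) and gene interiors (0.02) in cdc25-22, retrotransposon remains in rad3-deleted (0.06), and the differences at islands (0.44), centromeres (0.31), subtelomeres (1.07), the mating-type region (0.26), retrotransposon remains (0.17), convergent (0.22), divergent (0.29) and tandem (0.23) regions and gene interiors (-0.13). The construction shows why: 4 of 6 files change strain.

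For the listed files, one MAD gave 12 enriched and 1 depleted bins in cdc25-22 and 8 and 1 in rad3-deleted, and quantile normalization 38 and 2, and 26 and 1; both called islands lower (-0.12) and reversed divergent regions in rad3-deleted (-0.04). Loess and 2 kb bins gave 1 enriched bin in cdc25-22. The 1 bin enriched in rad3-deleted was lost (0) under normexp, without dim probes, with 500 bp bins, single probes, either A+T correction, the replicate block, the block with A+T, and a threshold of 0.01. Islands were called lower by rotation (-0.06, adjusted p = 0.003), but the slides gave -0.26, -0.49 and 0.58, a spread that rotation ignores. The subtelomere difference lost its call under centring on gene interiors (-0.20), 2 kb bins (-0.20), the A+T trend fitted away from islands (-0.20), the replicate block (-0.20), the block with A+T (-0.19) and an estimated correlation (-0.20). No setting but the matched files and the value table called a bin or a gene different between the strains.

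Leaving out listed arrays gave differences of -0.28 to 0.07 at islands and -0.63 to 0.02 at subtelomeres, 0 to 298 enriched and 0 to 116 depleted bins in cdc25-22, 0 to 0 enriched and 0 to 0 depleted in rad3-deleted, and 0 to 0 bins and genes higher or lower. Without the array listed as rad3-deleted replicate 3, in rad3-deleted, islands (-0.07), subtelomeres (-0.11), divergent (-0.12) and tandem (-0.01) regions and gene interiors (0.04) reversed. Over the 6 omissions, these classes ranged from -0.07 to 0.29 at islands, -0.11 to 0.52 at subtelomeres, -0.01 to 0.17 at tandem regions, -0.07 to 0.04 at gene interiors and -0.12 to 0.11 at divergent regions, and retrotransposon remains from -0.16 to 0.02. Retrotransposon remains reversed without listed rad3-deleted replicate 1 (0) or 2 (0.02), and the tRNA difference without listed cdc25-22 replicate 3 (0.07).

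For the matched files, before any array was left out, islands kept their direction and side of the threshold under all alternatives but an estimated correlation (0.26 to 0.50; 0.44 with adjusted p = 0.241 there), as did subtelomeres (0.93 to 1.12; 1.07 with adjusted p = 0.113 there). Under the same alternatives, bins higher in rad3-deleted ranged from 928 to 2264 and lower ones from 60 to 852. Normexp gave 99 enriched and 3 depleted bins in cdc25-22. The value table gave 119 and 3 there, 934 and 83 between the strains, 285 and 41 genes, and in cdc25-22 islands at 0.08 and gene interiors at 0. One MAD gave 504 and 95 in cdc25-22 and 252 depleted in rad3-deleted. Quantile normalization gave 576, 70 and 315, and reversed centromeres (-0.01) and 5S rRNA genes (-0.17) between the strains. Bins of 2 kb gave 89 and 1 in cdc25-22 and 736 and 175 in rad3-deleted, and bins of 500 bp 3214 and 1476 in rad3-deleted and 193 lower between the strains; here the number of bins differs by construction. Single probes gave 36 depleted in cdc25-22, 5370 and 2675 in rad3-deleted, and 2264 higher and 125 lower. A threshold of 0.01 gave 141 and 4 in cdc25-22, 928 higher and 60 lower. No minimum gave 49 depleted in cdc25-22 and 2483 and 2170 in rad3-deleted, and a minimum of 1 gave 19 and 0, and 467 and 1, by construction. Centring on gene interiors gave 364 depleted in rad3-deleted, 276 bins and 135 genes lower, the A+T trend fitted away from islands 257, 227 and 117, and no centring 744 bins and 497 genes lower. The replicate block gave 852 lower bins and the block with A+T 746. Genes with 500 bp flanks gave 687 higher and 437 lower, by construction from more probes.

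Leaving out matched arrays gave 0.34 to 0.54 at islands and 0.97 to 1.18 at subtelomeres, 1000 to 1764 bins higher and 113 to 911 lower, 219 to 527 genes higher and 28 to 431 lower. In cdc25-22 it gave 107 to 276 enriched and 2 to 21 depleted bins, and in rad3-deleted 1337 to 1775 and 382 to 910. A strain left with 2 arrays was assumed to vary like the other.

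With the files as listed, 41 values of genes named under the matched files reversed. They included coa2 in cdc25-22 (0.12), erg24 in rad3-deleted (-0.02), and between the strains mug147 (-0.67), SPAPJ695.01C (-0.33), SPAPJ695.02 (-0.29), wwm3 (-0.25), stg1 (-0.38), arv1 (-0.24), ddr48 (-0.20), pis1 (-0.53), rpa12 (-0.21), are1 (-0.47), htb1 (0.17), dhp1 (0.16), ctr4 (0.07), cnt6 (0.22), isa1 (0.12), rpl3602 (-0.19), rpl35 (0.34), rpl1701 (0.08), eno102 (-0.09), pdc201 (-0.27), pfk1 (0.17), fba1 (0.22), hsp16 (-0.23), suc22 (-0.17), ams2 (0.09), tos4 (0.14), mcm7 (-0.06), cdc27 (-0.11), rad4 (0.21), mcm6 (0.09), mre11 (-0.19), erg24 (-0.19), ght3 (-0.35), amt1 (-0.27), exg1 (-0.59), adg3 (0.17), meu13 (-0.04) and rec8 (0.01). None passed as listed (adjusted p = 1 for each difference).

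Of the other values under the matched files, 3579 for genes kept direction and side of the threshold, 414 lost a call and 84 gained one in the same direction; for classes these were 789, 61 and 16, and for gene lists 672, 13 and 8. Under the listed files, for classes 766 were kept, 45 lost and 55 gained a call, and for gene lists 648, 23 and 21. The dimmest channel was the input of the array listed as cdc25-22 replicate 2, where 84.9% of probes were well above background. Leaving out dim probes ended 2 gene calls and 1 gene list call under the listed files and 4 gene calls, 1 list call and 1 class call (centromeres, 0.24) under the matched files, and the islands difference under the matched files was 0.45.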

Other observations

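The value-table column that equals no scanner file correlated across bins with r of 0.17 to 0.39 with the arrays matched to cdc25-22 and 0.44 to 0.59 with those matched to rad3-deleted. At the 7 low rad3 probes its mean log2 ratio was 1.27, against 0.03 and -0.31 in the other cdc25-22 columns and 1.05, -1.11 and 1.18 in the rad3-deleted columns. A ratio does not show whether DNA was present there, and the column holds no single channel.

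Mitochondrial DNA lies outside the nuclear chromatin that Rad52 was mapped on. Its 66 probes stood at -0.19 ± 0.61 in arrays matched to cdc25-22 and -0.69 ± 0.30 in those matched to rad3-deleted (SD, n = 3 each, exact permutation p = 0.3). That test ignored the slides. Slide by slide, the rad3-deleted array was lower each time: -1.03 against -0.84, -0.55 against -0.07 and -0.49 against 0.36.

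After the strain means were removed, arrays of the same slide resembled each other, with r of 0.28, 0.20 and 0.17 across bins. For arrays of different slides r was -0.21 to -0.04. What remains of the arrays of a strain cancels in each bin, so positive values within slides force negative ones between slides. The negative values are thus no separate contrast.

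The remaining gene lists were called in no matched comparison. Of 11 heat shock genes, 1 was higher and 0 lower over all genes in cdc25-22 (1 and 0 adjusted over the list alone), 2 and 1 in rad3-deleted (2 and 1 adjusted over the list alone), and the chaperone gene hsp16 rose by 0.64 between the strains (adjusted p = 0.0151; 0.0715 without cdc25-22 replicate 1). Of 15 ergosterol genes, 1 and 0 were called in cdc25-22 over all genes (2 and 1 adjusted over the list alone), 4 and 1 in rad3-deleted (4 and 1), and erg24 (0.73; adjusted p = 0.00348) and spo9 (0.44; 0.0223) rose between the strains. Of 16 meiosis genes, 1 and 0 were called in cdc25-22 (2 and 1 adjusted over the list alone), namely rec15 at 0.69 ± 0.07, then 3 and 3 in rad3-deleted (3 and 3), and between the strains meu13 rose by 0.51 (0.0407) and rec8, the meiotic cohesin gene, fell by 0.49 (0.0237). Without cdc25-22 replicate 1 the adjusted p of spo9, meu13 and rec8 were 0.065, 0.116 and 0.0772. Of the subtelomeric helicase genes 1 was measured, too few for a list test. In rad3-deleted arrays the lists not called were ribosomal protein genes (14 higher, 13 lower over all genes; 14 and 13 adjusted over the list alone), glycolysis (4 and 0; 4 and 0), histones (0 and 0; 0 and 0), MBF targets (4 and 1; 4 and 1), replication machinery (4 and 7; 4 and 7), recombination and checkpoint genes (3 and 3; 2 and 2) and cell wall genes (4 and 3; 4 and 3). The list mean and median differed in sign for heat shock genes in cdc25-22 (0.05 and -0.01), and in rad3-deleted for ribosomal protein genes (0.01 and -0.03), MBF targets (0.03 and -0.01), recombination genes (0.03 and -0.02) and cell wall genes (0.10 and -0.09).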
